A study of Harpegnathos saltator with 36 samples.

How the data were processed

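Brains of the ant Harpegnathos saltator, without optic lobes, were profiled by strand-specific RNA sequencing of polyadenylated RNA, per the labels' protocols. Each library came from 1 brain, and each of the 18 brains was sequenced in 2 technical runs, which gives the 36 samples of the series. The submitters' processing notes name STAR 2.5.0b and DESeq2. The genome build and the counting tool are not given in the sources used here.

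The deposited count columns, 1 per brain, hold whole numbers of reads per feature for 19198 features, with no normalization. Their sums equal the summed gene counts of 2 runs of each brain, as recovered from the RPKM columns described next, so the technical runs were already added together and each brain counts as 1 replicate. No column had to be left out as belonging to another series. The deposited RPKM values are counts divided by gene length and by a library total. Within every column, the ratio of RPKM to count took 1 scale on odd-numbered rows and another on even-numbered rows, with a largest deviation of 5.42e-15 on the natural log scale. The scales matched the totals of the 18 CrzR runs on odd-numbered rows and of the 18 GFP runs on even-numbered rows, in column order and not the brain's own total. The divisor was between 0.176 and 1.23 times the brain's own gene count total. For this reason the RPKM columns gave no main result. They were used to recover gene lengths, to measure the shift between groups that they carry and in 2 alternative fits. The lengths came out within 1.46e-11 of a whole number for all 15941 genes with a count, and RPKM was recomputed from the counts, those lengths and each brain's own total. The authors' deposited comparison table gives, per the file headers, a mean signal over all samples (baseMean), a log2 fold change, a p-value and an adjusted p-value. DESeq2 1.42.0 with group as its only term, run on all deposited gene counts, gave fold changes that differed from that table by at most 0.000595 (log2) and the same number of calls, 4.

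The planned test assumed normalized values. Because the file holds counts, edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, group as the only term, two-sided) was run in R 4.3.3 on the counts of the 18 brains, 9 per siRNA. Of 18429 listed genes, the 10132 with a mean of at least 1 recomputed RPKM were tested, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The 769 rows for ribosomal, transfer, small nuclear and micro RNA stayed out of gene library sizes and were compared as shares of all counts. CPM of genes is TMM-scaled and relative to gene counts, and CPM of RNA classes is relative to all counts. Single values were compared by two-sided exact permutation tests over all 48620 assignments of 18 brains, and correlations by permutation tests with 100000 resamples. Analyses with limma 3.58.1 were alternatives. Total counts ran from 9741263 to 24166021 per brain, and the median standard error of a log2 fold change was 0.22.

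The edgeR steps were tested on simulated data for the CrzR against GFP comparison, in 5 simulated sets with 200 changed genes among 10132, drawn independently of each other. Over the sets they recovered 13.4% of 335 genes changed 1.5-fold, 57.0% of 335 genes changed 2-fold and 94.2% of 330 genes changed 4-fold, with 2 to 6 false calls per set. The adjusted p threshold is harder to pass when fewer than 200 genes change. The simulated genes also did not vary together as those of the brains do. These shares may therefore overstate the sensitivity in the real data.

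None of the 19198 row IDs matched the 14329 genes of the reference table of assembly Hsal_v8.6 (matches found: 0), and the files do not pair the IDs with gene names. The corazonin receptor, corazonin, vitellogenin and the gene lists and cell type markers fixed in advance are therefore not analysed here, and the extent of the knockdown is not reported. The rule for named genes was fixed before the data were examined, along with the threshold, the filter, the model terms and most of the other settings tried, and it took genes with a name. The test itself was set by the unit of the file. With none named and none past the threshold, the 2 genes with the smallest p in each direction are given by ID.

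Alternatives were the replicate number or groups of 3 replicate numbers as a block, other filters, scalings, thresholds, pseudocounts and tests, and leaving out each brain. Added after seeing the data were covariates for depth, for the first principal component and for small nuclear RNA, 2 surrogate variables (sva 3.50.0), the deposited RPKM columns with pseudocounts of 1 and 0.1, scaling by library size alone, edgeR's own filter and leaving out 4 shallow or low-factor brains. For share and axis values, CPM of gene counts, thinned counts, the 500 most variable genes and leaving out each brain were also added then.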

Results

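Harpegnathos saltator is an ant whose workers duel after the queen is lost, and some then become reproductive individuals (gamergates). Corazonin is a neuropeptide, and its receptor (CrzR) was the knockdown target. Dueling ants were taken on day 6 of the colony transition, after 3 days of dueling. They were kept in groups of 6, with 3 ants per siRNA, and the head of each received an injection of Dicer-substrate siRNA (volume 0.5 µl, concentration 5 µM) against CrzR or against GFP, a jellyfish gene that served as the control. Brains were collected 1 day later. The data comprised 9 brains per siRNA, each sequenced in 2 runs that the count table adds together. Total counts were 17082437 ± 5058592 in CrzR siRNA brains and 16961502 ± 4680823 in GFP siRNA brains (SD, n = 9 each). The shallowest brain had 9741263 counts and the deepest 24166021. Depth did not differ detectably between the groups (exact permutation test of log2 gene counts, p = 0.985). The closest pair of brains within a group differed far beyond counting noise (chi-square per degree of freedom 45.5), so no library was counted as a duplicate.

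The comparison asked which brain transcripts differ 1 day after knockdown of the corazonin receptor. The 2 genes with the smallest p-values in each direction were Hsal_02232 and Hsal_02466, which had higher counts after CrzR siRNA, and Hsal_01481 and Hsal_04932, which had lower counts. The files do not pair these IDs with names, and none of the 4 passed the correction over all genes. Because they were picked by p from these brains, their fold changes and group separation may be overstated. Hsal_02232 was at 65.6 ± 19.0 CPM in CrzR siRNA brains and 29.1 ± 11.3 CPM in GFP siRNA brains (SD, n = 9 each). Its fold change was 2.25, or 1.17 on the log2 scale (SE 0.23, edgeR adjusted p = 0.286), and 7 of 9 CrzR siRNA brains lay above the highest control. Hsal_02466 was at 101 ± 57.2 CPM against 31.8 ± 10.2 CPM, a log2 fold change of 1.66 (SE 0.36, edgeR adjusted p = 0.543), with 8 of 9 CrzR siRNA brains above the control median. Its remaining CrzR siRNA brain, replicate 5, was at 11.8 CPM, below the lowest control at 13.7 CPM. Hsal_01481 was at 26.9 ± 4.02 CPM against 49.9 ± 14.4 CPM, a log2 fold change of -0.89 (SE 0.16, edgeR adjusted p = 0.243). All 9 CrzR siRNA brains lay below the lowest control for Hsal_01481. It was the only 1 of the 10132 tested genes whose groups did not overlap on log CPM, where chance gives 0.00411% of genes, or 0.417 genes. Hsal_04932 was at 153 ± 24.7 CPM against 242 ± 62.2 CPM, a log2 fold change of -0.67 (SE 0.15, edgeR adjusted p = 0.543), with all 9 CrzR siRNA brains below the control median. Recovered gene model lengths were 14148 bases for Hsal_02232, 4901 for Hsal_02466, 2822 for Hsal_01481 and 8062 for Hsal_04932.

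**Figure D1:**
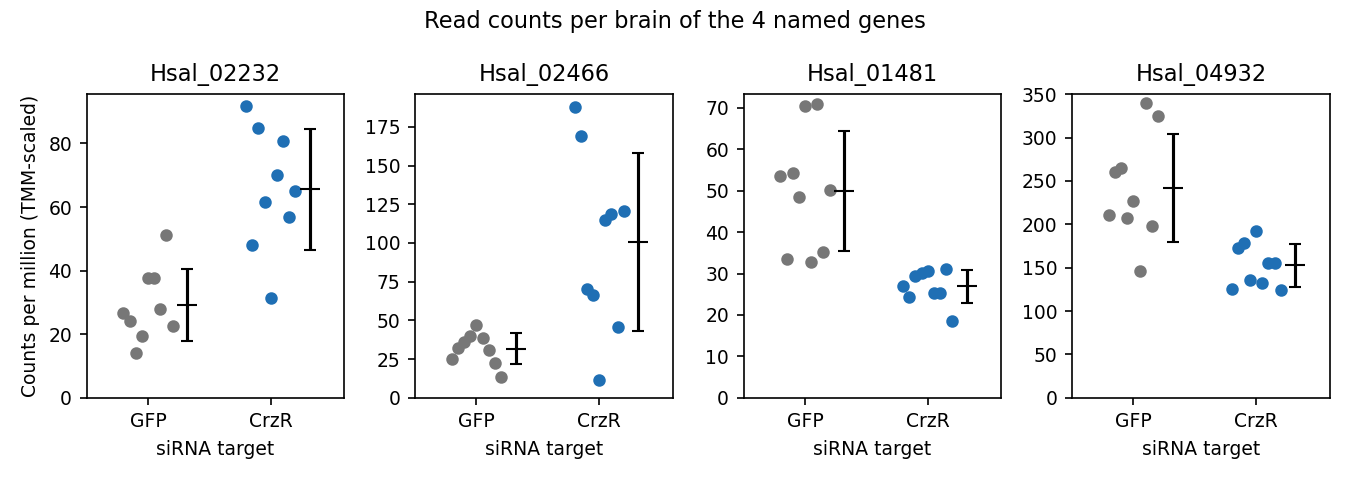
CPM (TMM-scaled, vertical axis) of the 4 genes given by ID in each brain, by siRNA target (horizontal axis). Each point is 1 brain, and the bars give the mean and SD of 9 brains. For Hsal_01481 every CrzR siRNA brain is below every GFP siRNA brain.

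Across the transcriptome, edgeR called 0 of 10132 genes at adjusted p under 0.05 and 0 at 0.10. With covariates chosen after seeing the data, edgeR still called 0 at 0.05. At 0.10 it gave 688 genes with depth and 1045 with the small nuclear RNA share as a covariate. The first principal component or 2 surrogate variables as covariates gave 0 at 0.10. Of 100 splits of the brains, the real one included, 5 gave at least 688 with depth and 2 at least 1045 with the RNA share. At an unadjusted p under 0.05 there were 820 genes (8.09%), of which 474 were higher and 346 lower after CrzR siRNA. Independent unchanged genes would give 507, but genes vary together, and 22 of 100 splits of the brains, the real one included, gave 820 or more. DESeq2 called 3 of the same 10132 genes (2 higher, 1 lower), and limma voom with array weights called 4 (1 higher, 3 lower). DESeq2's 3 genes were Hsal_02232 (adjusted p = 0.00369), Hsal_02466 (adjusted p = 0.0106) and Hsal_01481 (adjusted p = 0.0019). For limma voom, the adjusted p was 0.0137 for both Hsal_02232 and Hsal_01481 and 0.0473 for Hsal_04932. Without CrzR siRNA replicate 5, edgeR called Hsal_02232 and Hsal_02466, and without GFP siRNA replicate 8 it called Hsal_02232 and Hsal_01481. Scaling by library size alone raised the median log2 fold change of all genes from 0.0011 to 0.10 and gave 848 genes at unadjusted p under 0.05, of which 733 were higher.

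Of the tested genes, 163 had a fitted log2 fold change beyond 1 in either direction (77 higher, 86 lower). The biological coefficient of variation between brains was 0.394. The labels do not say which ants were kept together, so sorting the brains by replicate number is an assumption. In groups of 3 replicate numbers (1 to 3, 4 to 6, 7 to 9), the log2 difference for Hsal_01481 was -0.78, -0.75 and -1.03. For Hsal_02232 it was 1.77, 0.76 and 1.06, and for Hsal_04932 it was -0.63, -0.33 and -0.95. For Hsal_02466 the values were 2.09, 0.10 and 2.04.

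The authors' deposited table, from a DESeq2 comparison of the same brains, listed 4 genes at adjusted p under 0.05, 3 of them higher and 1 lower after CrzR siRNA. In the authors' deposited table the adjusted p was 0.00656 for Hsal_02232, 0.0184 for Hsal_02466 and 0.00299 for Hsal_01481. Hsal_04932 had an adjusted p of 0.0997 in the authors' deposited table. The remaining gene of the 4 is left without its ID, because its edgeR p was not among the 2 smallest in its direction. This gene had an adjusted p of 0.0341 in the authors' deposited table. In the counts it was at 873 ± 962 CPM in CrzR siRNA brains and 141 ± 60.5 CPM in GFP siRNA brains (SD, n = 9 each), and its edgeR adjusted p was 0.543. Its log2 difference was 1.98 in replicates 1 to 3, -0.96 in replicates 4 to 6 and 4.14 in replicates 7 to 9. Over the 10132 tested genes, fold changes from edgeR and from the authors' deposited table correlated across genes with r = 0.962, and 98.4% had the same sign.

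Non-coding RNA classes are the other named features of the table. Small nuclear RNA took 572 ± 457 CPM of all counts in CrzR siRNA brains and 604 ± 499 in GFP siRNA brains (SD, n = 9 each, exact permutation p = 0.970). Ribosomal RNA took 1.35 ± 0.888% and 1.14 ± 0.744% of counts (exact permutation p = 0.597). Transfer RNA took 33.5 ± 33.2 and 29.5 ± 21.1 CPM (exact permutation p = 0.846), and micro RNA loci 7.90 ± 3.11 and 8.36 ± 2.54 (exact permutation p = 0.614). Over these 4 classes every Benjamini-Hochberg adjusted p was 0.970. The locus hsal-mir-45 held 71.9% of all counts on micro RNA loci, with 6.02 ± 3.12 CPM after CrzR siRNA and 5.96 ± 1.92 after GFP siRNA (exact permutation p = 0.783). For hsal-mir-80 the values were 0.638 ± 0.580 and 0.648 ± 0.495 (exact permutation p = 0.828, adjusted p = 0.828 for both loci). Libraries selected for polyadenylated RNA hold little of these classes, so the values describe what passed the selection.

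The largest axis of variation among the brains followed the depth of the libraries. The first principal component held 43.1% of the variance of log CPM. Its scores were 14.2 ± 38.2 in CrzR siRNA brains and -14.2 ± 42.1 in GFP siRNA brains (SD, n = 9 each). A test that ignored depth found no detectable difference between the groups (exact permutation p = 0.153, adjusted p = 0.459 over 3 components). The second component held 14.3% (exact permutation p = 0.640) and the third 6.07% (exact permutation p = 0.529). The first component rose with the depth of the brain's library, with r = 0.80 (permutation p = 5e-05) and rho = 0.82 (permutation p = 7e-05) over 18 brains. Without the 2 brains farthest from the median depth r was 0.78, and within the groups it was 0.85 for CrzR siRNA and 0.88 for GFP siRNA. Of the 10132 genes, 5671 (56.0%) followed depth at an edgeR adjusted p under 0.05, 3194 of them higher in deeper libraries and 2477 lower. The share of small nuclear RNA fell with depth (r = -0.91, rho = -0.86, without 2 brains r = -0.86), as did that of transfer RNA (r = -0.91, rho = -0.92, without 2 brains r = -0.85). For small nuclear RNA the permutation p was 1e-05 for r, the smallest that 100000 resamples can give, and 3e-05 for rho. For transfer RNA both were 1e-05. The first component went with the small nuclear RNA share at r = -0.81 (permutation p = 4e-05), rho = -0.85 (permutation p = 1e-05) and r = -0.81 without 2 brains. The Benjamini-Hochberg adjusted p of these 4 relations, among 9 computed, was at most 0.00016. Ribosomal RNA, the largest of the classes, was less closely tied to depth, with r = -0.56 (permutation p = 0.0168, adjusted p = 0.019) and rho = -0.52 (permutation p = 0.0302, adjusted p = 0.034). Its r was -0.42 without 2 brains, and it was -0.24 within CrzR siRNA brains and -0.94 within GFP siRNA brains. For the share of micro RNA loci r was -0.64 (permutation p = 0.0046, adjusted p = 0.0059) and rho -0.57 (permutation p = 0.0143, adjusted p = 0.0184), with r = -0.52 without 2 brains. The other 3 relations were of counts in place of shares, with r = -0.76 for small nuclear RNA, -0.77 for transfer RNA and 0.27 for micro RNA loci (permutation p = 0.00029, 0.00016 and 0.279).

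**Figure D2:**
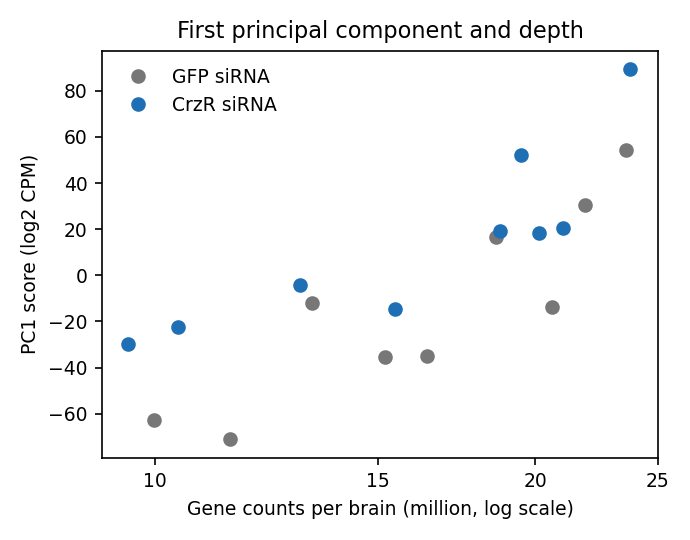
First principal component score (log2 CPM, vertical axis) against gene counts per brain (horizontal axis, log scale). Each point is 1 brain, coloured by siRNA. The score rises with depth in both groups (r = 0.85 for CrzR siRNA and 0.88 for GFP siRNA).

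The deposited RPKM columns carried a shift between the groups that differed by row. Over tested genes on odd-numbered rows, the median log2(RPKM + 1) was 0.18 higher in CrzR siRNA brains, and on even-numbered rows 0.0027 higher. Recomputed with each brain's own total, the shifts were 0.10 and 0.094. A limma fit to the RPKM columns as deposited gave 0 genes at adjusted p under 0.05 and 73 at unadjusted p under 0.05. The same limma fit to RPKM recomputed with each brain's own total gave 0 and 920 genes, 822 of the 920 higher after CrzR siRNA. Neither limma fit used TMM scaling. In edgeR at unadjusted p under 0.05, 733 of 848 genes were higher with library size alone and 474 of 820 with TMM scaling.

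**Figure D3:**
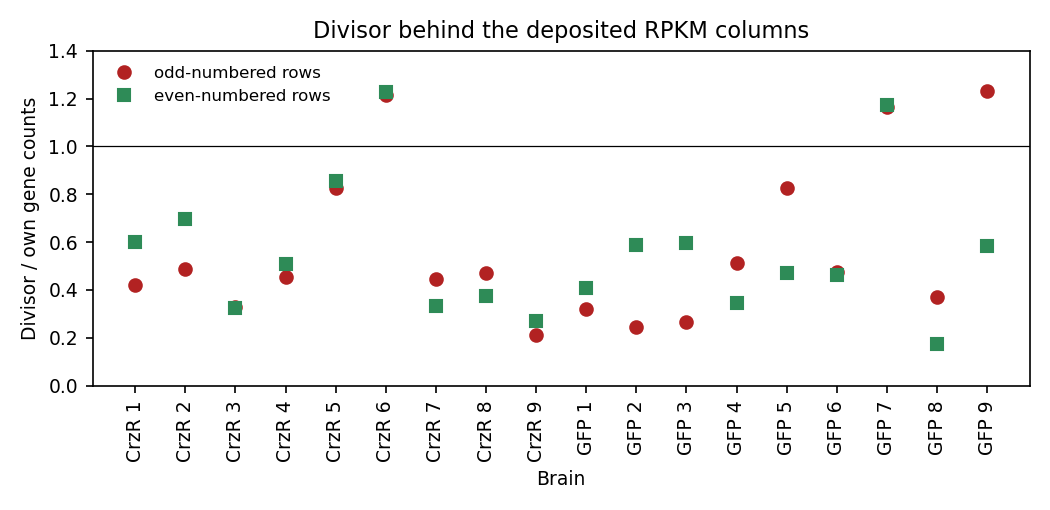
Library total by which the deposited RPKM values were divided, relative to the brain's own gene counts (vertical axis), for each of the 18 brains (horizontal axis). Circles are odd-numbered rows and squares even-numbered rows. The line at 1 marks a brain's own total, and the ratios run from 0.176 to 1.23.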

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

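Of the tests in this part, the removal of gene length trends and the DESeq2 splits were set before their results were seen, and the others after. Chance marks about 1 in 20 groups, and 2 of the 28 groups of values examined held a brain far from the rest. CrzR siRNA replicate 6, the shallowest library, had 1685 CPM on small nuclear RNA, where the other 8 brains of its group had 235 to 758. The same brain had 114 CPM on transfer RNA, against 12.0 to 50.1 in the others. These values were examined without taking logs, unlike in the group tests of the classes. Both shares fell with depth (r = -0.91 each), so the 2 flags are not independent.

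The group difference itself was set against other splits of the 18 brains. The real split gave 820 genes at unadjusted p under 0.05, and 22 of 100 splits, the real one included, gave as many, the highest other 3852, so chance is not excluded. The 0 edgeR calls cannot be set against splits, since all 100 splits give at least 0 whatever the data, and the highest other gave 1. For DESeq2, 8 of 40 splits called at least the real 3 genes, and the highest other called 13. Splits with several times the real count point to a structure among the brains other than the siRNA. Removing each brain's trend over gene length gave 873 genes, 651 of them among the 820, which argues against a length trend as the whole source of the count, but the balance turned from 474 higher and 346 lower to 409 higher and 464 lower.

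The main axis of the brains followed depth. Thinning every brain to the shallowest left r = 0.80 (permutation p = 5e-05), which argues against fewer counted reads, and removing length trends left r = 0.81 (permutation p = 2e-05). RNA composition of the libraries is a candidate explanation that stays open. The axis went with the small nuclear RNA share (r = -0.81), also within CrzR siRNA brains (exact permutation p = 0.0169) and GFP siRNA brains (exact permutation p = 6.89e-05). That share itself fell with depth in both groups (r = -0.89 for CrzR siRNA and -0.95 for GFP siRNA). These correlations therefore cannot tell composition apart from anything else that goes with depth. The ribosomal RNA share was not set against the axis, and it went with depth at r = -0.94 in GFP siRNA brains and -0.24 in CrzR siRNA brains, and what sets these shares was not tested. A test that ignored depth could not tell the siRNA as the cause apart from chance on this axis (9 brains per group, exact permutation p = 0.153). After removing the group means, the correlation of the axis with depth was 0.86, against 0.80 before. A group difference at equal depth was not tested.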

How the results depend on the processing

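Covariates, deposited RPKM, scaling by library size alone, edgeR's own filter, the removal of 4 brains and all alternatives for RNA shares and the axis were chosen after seeing the data. The count of 0 genes held under 19 of 21 alternatives that left out no single brain. The exceptions were DESeq2 with 3 genes (2 higher, 1 lower) and limma voom with array weights with 4 (1 higher, 3 lower); the cause was not tested. Leaving out each brain gave 0 to 2 calls, 0 to 2 higher and 0 to 1 lower, with 2 calls only without CrzR siRNA replicate 5 or GFP siRNA replicate 8. The 820 genes at unadjusted p under 0.05 became 1329 with no filter (more genes tested), 2274 with limma voom, and 2779 with depth and 2919 with small nuclear RNA share as a covariate; the cause was not tested. Limma gave 73 with RPKM as deposited (74 with a pseudocount of 0.1) against 920 (933) with RPKM recomputed, so the divisor of the deposited columns lowers the count. Leaving out each brain gave 406 to 2053, with 504 without CrzR siRNA replicate 4, 406 without 8, 542 without GFP siRNA replicate 2, 517 without 4 and 472 without 7, and 2053 without 8. With depth as a covariate 688 genes passed adjusted p under 0.10, and 5 of 100 splits of the brains gave as many, the highest other 2726, so chance is not excluded. With small nuclear RNA share 1045 passed it, and 2 of 100 splits gave as many, the highest other 3509. That share is under 0.05, but this was 1 of 4 covariate fits chosen after seeing the data. The other 2 (first component, surrogate variables) gave 0 at 0.10. Both are computed from the same expression values and can take up part of a group difference, so their 0 genes decide nothing here. Without the 4 shallow or low-factor brains 590 genes were under 0.05 unadjusted and 0 called. The authors' deposited table lists 2 genes at adjusted p under 0.01 and 6 at 0.10.

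Replicate numbers showed no clear pairing of the brains: 3 of 9 same-numbered pairs correlated over 0.1 (range -0.55 to 0.75). Not every brain was closest to its own number, though the brains numbered 8 were closest to each other. These correlations also carry the axis that followed depth, so they cannot exclude pairing. With the replicate block, 0 genes were called and 1222 passed unadjusted p under 0.05. The 4 named genes kept their direction under every alternative that tested them (a mean of at least 5 RPKM left out Hsal_02232), with adjusted p from 0.0019 to 1.00 over tests. No RNA class difference or axis correlation changed its side of the threshold, with r between 0.74 and 0.84 without single brains. Single runs, the gene lists, the receptor and vitellogenin were not run. Most simulated 1.5-fold changes went undetected.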

Other observations

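The tests here were chosen after the results were seen. Some genes differed widely between brains of the same group. Among 7549 genes with a mean of at least 10 CPM, 96 spanned over 10-fold within each of the groups and 15 spanned over 100-fold within each, with values under 0.1 CPM set to 0.1. The widest ran from 95 counts in the lowest brain to 920851 counts in GFP siRNA replicate 1, where it took 4.91% of all counts. It was chosen after its values were seen and is left without its ID because it was not among the genes taken for their small p.

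A pair of genes with consecutive IDs, also chosen after their values were seen, had over 20 counts in 3 brains, all of CrzR siRNA. Of the 4 genes with over 20 counts in exactly 3 brains and under 10 elsewhere, the other 2 each had them in 2 CrzR siRNA brains and 1 GFP siRNA brain. The first gene had 136, 664 and 1939 counts and the second 58, 238 and 1524 in replicates 1, 7 and 8, and the other 15 brains had at most 7. Fisher's exact test of 3 of 9 against 0 of 9 brains gave p = 0.206, the smallest that 3 such brains of 18 allow, so placement by chance was left undecided. As for carry-over of another tissue, 0 other genes had over 20 counts in the same 3 brains and under 10 elsewhere. Only 4 genes met that rule in any 3 brains, and a gene with more reads elsewhere would fail it. The rule therefore cannot decide on carry-over. An inherited difference between ants may underlie the pattern and was not tested.

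Genes with consecutive IDs varied together between brains. Over 7591 such pairs the median correlation of deviations from the group means was 0.16, against -0.02 to 0.04 in 1000 shuffled orders. No explanation for it was tested.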
